A study of Mus musculus with 6 samples.

How the data were processed

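The libraries were made from polyA RNA of epididymal white adipose tissue of obese mice, 3 labelled WT (floxed Ilf3 without deletion in adipocytes) and 3 labelled KO (adipocyte knockout of Ilf3). Mice were 8 weeks old when a high-fat diet (60% fat) began, and they were fed it for 16 weeks, per the labels' protocols. Samples were grouped by the genotype given in their labels, and replicates were numbered within each group by the order of deposit, so the numbers do not pair WT with KO. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which could be technical.

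One table of the whole series was deposited, with raw counts per gene and FPKM per gene for each library, per the file headers. The counts are whole numbers that are not normalized. The deposited FPKM values are counts scaled for gene length and for library size. For each gene, the length implied by count and FPKM differed between libraries by a factor of at most 1.00 (largest ratio 1.00086), so both columns come from 1 count. The FPKM columns entered only this check. Base calling with CASAVA 1.8, alignment with HISAT2 to mm10, SAMtools 1.3.1 and edgeR are named in the submitters' processing notes, which do not give the role of each tool. The program that counted reads, its strand setting, its treatment of reads with several positions, and the gene annotation are not given in the sources used here. Of the gene identifiers in the table, 99.4% are in GENCODE M21, and 99.4% of those have the same coordinates there. Coordinates are those of the table, in mm10 per the submitters' processing notes. Values of near-identical paralogs (Ifit3 and Ifit3b, the haemoglobin genes) and of overlapping or antisense genes are uncertain, because the split of shared reads is not known. Columns of values without a sample numbered 0. The columns of WT replicate 1 lack the group that its sample title carries and were matched by the number 1292 alone, which no other title holds.

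The table holds 55487 genes. A symbol carried by several identifiers, as 120 symbols are, was taken at the identifier with the most counts. Total counts per library were 12669584, 13435655 and 13437040 for WT replicates 1 to 3 and 17806107, 16294069 and 13092967 for KO replicates 1 to 3. Levels per library are given in CPM computed with the total count times the TMM factor as library size, as mean ± SD with n = 3. Reads carry no molecular identifiers, so any counting interval covers counting error only.

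Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, filterByExpr by group (15780 genes tested) and a model with genotype alone. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are KO minus WT and are followed by ± their standard error, taken from the fold change and its F statistic. Adjusted p-values of single genes come from this test unless DESeq2, the exact test or limma is named. The test, the 37 gene lists, the rule for naming genes and all alternatives except the joint removal of WT replicate 1 and KO replicate 2 were fixed before the data were examined. List members numbered 643, of which 643 were matched to the table, older symbols included. Each list was tested with camera of limma 3.58.1 on the edgeR object, with a preset correlation between genes of 0.01 and adjustment over the 36 lists with tested members. Camera with a correlation estimated from the data, and fry, were run beside it.

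Genes named in the text are Ilf3, Fads1, Fads2 and Elovl5 in any case. A further part of the rule took the 10 largest changes each way among changed genes with assigned names, a mean of at least 1 CPM and groups that do not overlap; no gene met it. In each list past the threshold, and in the list of polyunsaturated fatty acid (PUFA) synthesis, the 4 tested members with the smallest p are named, and for other lists up to 2. The most abundant marker genes are named where a mixed sample was tested. Genes outside the rule are said to have been chosen after their values were seen.

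The alternatives were RLE, upper quartile and library size factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the exact test of edgeR, limma voom with sample weights, each replicate left out, the libraries whose titles end in a 3-digit number (1 WT and 3 KO), a minimum log2 fold change of 1, and removal of mitochondrially encoded genes. Removal of WT replicate 1 and KO replicate 2 together was added after their marker genes had been seen. The expression filter was applied anew to each set of libraries, so the tested members of a list can differ between sets. Titles end in 1292, 1294 and 899 for the WT replicates in order, and in 894, 895 and 896 for the KO replicates. The labels do not say what these numbers mean. If they mark batches or cohorts, differences between those are partly confounded with genotype and could not be separated from it.

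The procedure was tested on simulated data drawn from the means, library sizes and spread of these 6 libraries, with 15780 genes tested. It recovered 1 of 73 genes changed 2-fold, 24 of 67 changed 4-fold and 46 of 60 changed 8-fold, with 4 unchanged genes called. With the spread of the 4 libraries left after removing WT replicate 1 and KO replicate 2, it recovered 23 of 73, 55 of 67 and 56 of 60, with 10 unchanged genes called. The simulated data still had all 6 libraries there, so these are not recoveries for a comparison of the 4 libraries. A list raised 2-fold in the simulated KO libraries had an adjusted p of 1.33e-17 with the preset correlation and 0.0401 with an estimated correlation, and 0 other lists passed. Genes were simulated independently of each other, while the correlation estimated for interferon-stimulated genes in the real data was 0.62. The simulation therefore cannot show how often either setting falsely calls or misses lists of correlated genes. Figures were drawn with matplotlib 3.10.9.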

Results

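Messenger RNA was sequenced from epididymal white adipose tissue, the visceral fat depot beside the testis, of mice fed a high-fat diet. The series compares mice with floxed Ilf3 (WT, n = 3) with mice lacking Ilf3 in adipocytes (KO, n = 3), and its title ties the knockout to PUFA synthesis. Ilf3 encodes a protein that binds double-stranded RNA. Total counts ranged from 12669584 in WT replicate 1 to 17806107 in KO replicate 1. Mitochondrially encoded genes took 14.5% of the counts of WT replicate 1, and 4.81% and 5.50% in WT replicates 2 and 3. Their share was 7.31%, 7.71% and 7.81% in KO replicates 1 to 3.

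WT replicate 1 and KO replicate 2 stood apart from the other 4 libraries. In WT replicate 1 the B cell gene Cd19 reached 291 CPM and the T cell receptor gene Trac 126 CPM, against at most 0.876 and 1.98 CPM in any other library. The mesothelial gene Upk3b was at 0.239 CPM there and at 13.3 to 150 CPM in the others. KO replicate 2 held 2865 CPM of Crisp1, a secreted protein of the epididymis, and 359 CPM of the smooth muscle gene Cnn1, against at most 2.07 and 5.66 CPM elsewhere. Leptin (Lep) was at 154 CPM in WT replicate 1 and 253 CPM in KO replicate 2, and at 578 to 1701 CPM in the other libraries. The mean correlation of log2 CPM with the other libraries was 0.870 for WT replicate 1 and 0.919 for KO replicate 2, and 0.931 to 0.940 for the rest. The first principal component (48.3% of the variance) set WT replicate 1 apart and the second (21.4%) KO replicate 2.

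The level of Ilf3 itself did not separate the groups. Ilf3 (ENSMUSG00000032178; chromosome 9, 21367871 to 21405361) was at 40.6, 35.4 and 40.5 CPM in WT replicates 1 to 3 and at 34.3, 38.2 and 36.8 CPM in KO replicates 1 to 3. Group means were 38.8 ± 2.95 and 36.4 ± 1.98 CPM (SD, n = 3). The log2 fold change was -0.09 ± 0.16, with a 95% interval of -0.48 to 0.30 (adjusted p = 0.997, edgeR). The lower end of that interval is a drop of 28.1%. Counts per library were 464 to 659, so depth was not the limit. Counts cover the whole gene, so loss of a part of the transcript would not show here, and cells other than adipocytes also contribute reads. Since this gene did not set the groups apart, directions are given for the libraries as labelled.

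Plin5, a perilipin that coats lipid droplets and ties them to mitochondria, was at 12.6, 17.3 and 24.0 CPM in WT and at 4.99, 5.91 and 5.22 CPM in KO-labelled libraries (log2 fold change -1.73 ± 0.31). Ehhadh, an enzyme of peroxisomal fatty acid oxidation, was at 63.2 ± 5.89 and 100.3 ± 1.34 CPM (0.67 ± 0.15). Fdft1, the squalene synthase of the cholesterol pathway, had a log2 fold change of 1.25 ± 0.37, and Pparg, the master regulator of adipocyte differentiation, one of 0.48 ± 0.19. In each of these 4 genes, which come from 4 lists that did not pass, every KO-labelled library lay on one side of every WT library. They are among the members with the smallest p, which favours such separation, and others of that rank (Cidea, Acaca and Me1) overlapped. None of the 4 passed the edgeR test (adjusted p = 0.997 for each), and Plin5 passed in DESeq2 (adjusted p = 0.0101). Ccdc50 (chromosome 16, 27388869 to 27452218), which binds ubiquitin, was chosen after its values were seen. It was at 28.7 ± 6.21 CPM in WT and 118 ± 26.1 CPM in KO-labelled libraries (2.05 ± 0.26), with an adjusted p of 5.45e-06 in DESeq2 and 8.57e-06 in the exact test. Ehhadh and Ccdc50 lie on chromosome 16 with Adipoq between them, and sequence variants there were not examined.

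Of 15780 genes tested, 0 changed by edgeR's quasi-likelihood test, and the smallest adjusted p was 0.997. At an unadjusted p under 0.05 there were 512 genes (247 higher and 265 lower in KO-labelled libraries), where chance alone gives 789. DESeq2 called 13 genes (7 higher, 6 lower). It had 847 unadjusted among 31014 genes with a p-value, so the 789 expected for 15780 genes does not apply to it. The exact test called 2 (Ccdc50 and Gm28539, both higher, with 650 unadjusted), and limma voom with sample weights called 0 (1163 unadjusted). KO-labelled libraries lay wholly above WT for 634 genes and wholly below for 509, which is 7.24% of the genes tested, where chance gives 10%. The spread between libraries corresponded to a coefficient of variation of 42.7%, and of 33.1% without WT replicate 1. Simulated counts with this spread recovered 1.37% of 2-fold, 35.8% of 4-fold and 76.7% of 8-fold changes. Most 2-fold and 4-fold changes were thus missed there. Genes were drawn independently, each with 1 spread for all libraries. The simulation therefore lacks joint shifts of many genes within 1 library, as in WT replicate 1 and KO replicate 2. Without WT replicate 1 the count was 0 (1219 unadjusted), and without WT replicate 1 and KO replicate 2 together it was 0 (1173 unadjusted).

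PUFA synthesis was the question named by the study. Fads2 (chromosome 19, 10062765 to 10101746), the delta-6 desaturase that starts the pathway, was at 14.7, 7.86 and 9.26 CPM in WT and at 12.8, 248 and 12.5 CPM in KO-labelled libraries. Fads1 (chromosome 19, 10182888 to 10196877), the delta-5 desaturase, was at 73.6, 51.9 and 44.5 CPM and at 71.2, 222 and 57.0 CPM. Elovl5 (chromosome 9, 77917364 to 77984519), which elongates PUFA, was at 143 ± 11.7 and 156 ± 35.1 CPM. The log2 fold changes were 3.12 ± 1.25 for Fads2, 1.05 ± 0.55 for Fads1 and 0.12 ± 0.22 for Elovl5, and without KO replicate 2 they were 0.25 ± 0.35, 0.18 ± 0.28 and 0.29 ± 0.20; Elovl5 was -0.01 without KO replicate 3. Fads6 (2.24 ± 0.98) and Hacd4, a dehydratase of fatty acid elongation (1.08 ± 0.55), were likewise highest in KO replicate 2, at 37.7 and 43.7 CPM, and had log2 fold changes of 0.26 ± 0.43 and 0.44 ± 0.48 without it. Of 15 tested members of the list, 0 rose and 0 fell over all genes and 0 passed adjusted over the list alone; 12 had a positive log2 fold change and 3 a negative one. As a list PUFA synthesis rose (median 0.18, adjusted p = 0.0109, camera), with adjusted p = 0.855 with an estimated correlation. The call ended without KO replicate 2 (median 0.16), and without WT replicate 1 camera turned to the other direction (median 0.07); the list's adjusted p ranged from 0.000621 to 0.976 over the alternatives that kept camera with the preset correlation, and was 0.995 by fry. Crisp1, of the epididymis, and Cnn1, of smooth muscle, were high in the same KO replicate 2.

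**Figure D1:**
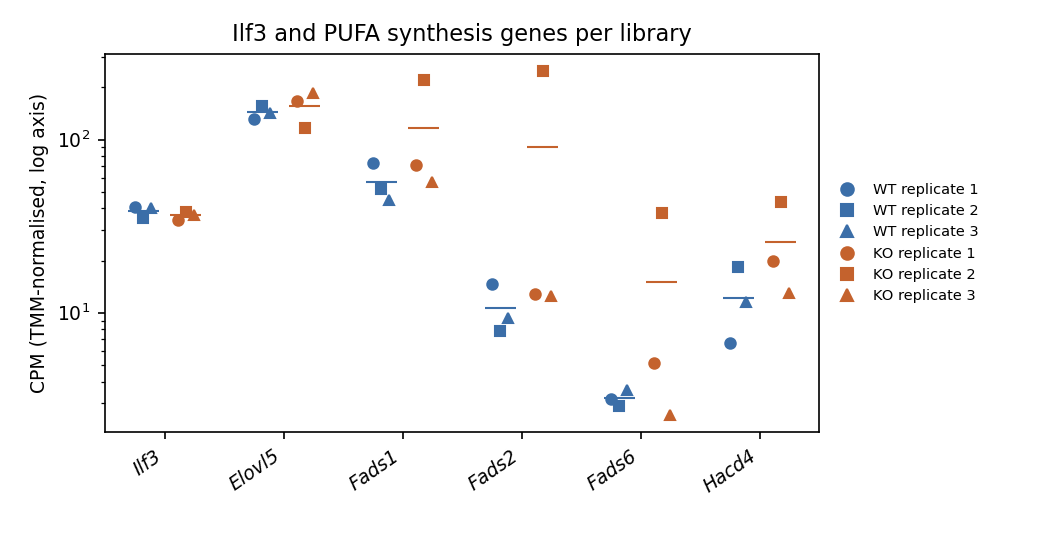
CPM per library on a log axis for Ilf3, Elovl5, Fads1, Fads2, Fads6 and Hacd4, with WT in blue, KO-labelled libraries in orange, a symbol per replicate and a line at each group mean. Ilf3 overlaps between groups, and the Fads2 value of 248 CPM is that of KO replicate 2 while the other 5 libraries lie between 7.86 and 14.7 CPM.

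Interferon-stimulated genes, the antiviral programme that double-stranded RNA can trigger, rose as a list in KO-labelled libraries. Of 29 members tested, 25 had a positive log2 fold change (median 0.55, adjusted p = 4.73e-11, camera; adjusted p = 0.855 with an estimated correlation). Ifit3, an interferon-induced antiviral protein, was at 22.8 ± 6.37 CPM in WT and 59.2 ± 22.3 CPM in KO-labelled libraries (1.38 ± 0.37). Ifit3b (1.42 ± 0.36), which shares reads with Ifit3, Rtp4 (1.29 ± 0.34), which lies on chromosome 16 between Ehhadh and Ccdc50, and Oasl2 (1.03 ± 0.30) also lay above WT in all 3 KO-labelled libraries. No member passed the edgeR test over all genes, and 0 passed adjusted over the list alone. Over the whole list the groups overlapped. The median deviation of its members from their mean log2 CPM was 0.19, -0.69 and -0.59 in WT replicates 1 to 3. In KO replicates 1 to 3 it was 0.47, -0.37 and 0.68, so KO replicate 2 lay below WT replicate 1. By camera with the preset correlation alone, the list stayed past the threshold, with the same direction, in every set of libraries run. Its median moved to 1.02 without WT replicate 1, to 0.34 without KO replicate 3 and to 1.17 without WT replicate 1 and KO replicate 2 together.

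Endothelial genes and genes of resident or alternatively activated macrophages also rose as lists. Emcn, an endothelial surface glycoprotein, was at 41.7, 38.5 and 39.6 CPM in WT and at 69.1, 50.3 and 59.4 CPM in KO-labelled libraries (0.58 ± 0.18), and Vwf, von Willebrand factor, had a log2 fold change of 0.98 ± 0.32. Tek (0.47 ± 0.24) and Flt1 (0.33 ± 0.20), receptors for angiopoietins and VEGF, came next; Tek was 0.26 without KO replicate 1. Of 13 endothelial genes tested 12 were positive (median 0.30, adjusted p = 0.000842, camera; adjusted p = 0.855 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Without KO replicate 1 the endothelial call ended (median 0.08), and without KO replicate 2 the median was 0.45. Of 10 resident macrophage genes 9 were positive (median 0.59, adjusted p = 0.00182, camera; adjusted p = 0.855 with an estimated correlation), among them the lectin Mgl2 (0.90 ± 0.40), the hyaluronan receptor Lyve1 (0.56 ± 0.29) and the haemoglobin scavenger receptor Cd163 (0.76 ± 0.51). Timd4, a receptor for dying cells, was the exception (-2.61 ± 1.47), with 32.8 CPM in WT replicate 1, and was 1.29 ± 0.48 without that library. Cd163 was 0.17 ± 0.45 without KO replicate 2, Mgl2 was 0.41 without KO replicate 1 and Lyve1 was 0.35 without WT replicate 1. The macrophage call, also with 0 members past either adjustment, ended without WT replicate 1 (median 0.41), without WT replicate 3 (0.49) and without KO replicate 1 (0.17).

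Mesothelial genes, which mark the lining of the visceral cavity, and eicosanoid genes rose as lists, and several of their leading members were high in KO replicate 2. All 10 mesothelial genes were positive (median 1.59, adjusted p = 3.19e-06, camera; adjusted p = 0.855 with an estimated correlation). Keratin 19 (Krt19) was at 0.558, 19.2 and 5.13 CPM in WT and at 2.30, 218 and 30.1 CPM in KO-labelled libraries (3.35 ± 1.69), and was 0.96 ± 1.48 without KO replicate 2. Krt18 (2.73 ± 1.47), Krt8 (2.49 ± 1.53) and the membrane glycoprotein Gpm6a (1.71 ± 0.95) followed; Krt18 and Krt8 were 0.95 ± 1.39 and 0.67 ± 1.49 without KO replicate 2 and 5.11 and 4.41 without WT replicate 2, and Gpm6a was 0.80 without KO replicate 3. Keratins 8, 18 and 19 are also made by duct epithelium, and Crisp1 stood at 2865 CPM in the same KO replicate 2. Without WT replicate 1, in which Upk3b was at 0.239 CPM, the mesothelial call ended (median 1.05), and without KO replicate 3 the median was 0.66. Among eicosanoid genes the prostaglandin synthase Ptgs2 was at 1025 CPM in KO replicate 2 and at 0.398 to 5.82 CPM elsewhere (6.51 ± 2.58; -0.48 ± 1.03 without that library). Ptges (1.74 ± 0.69), Ptgs1 (1.85 ± 0.80) and the lipoxygenase Alox12 (1.54 ± 0.62) were the other leading members, and Alox12 alone of the 4 lay above WT in all 3 KO-labelled libraries. Without KO replicate 2 Ptges was 0.79 ± 0.52 and Ptgs1 0.41 ± 0.40, and without KO replicate 1 Alox12 was 0.84. Of 22 eicosanoid genes 15 were positive (median 0.37, adjusted p = 0.000773, camera; adjusted p = 0.855 with an estimated correlation). That call ended without WT replicate 1 (median 0.57) and without WT replicate 1 and KO replicate 2 together (0.12), and medians were 0.15 without KO replicate 1 and 0.23 without KO replicate 2. In both lists 0 members passed over all genes or adjusted over the list alone.

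**Figure D2:**
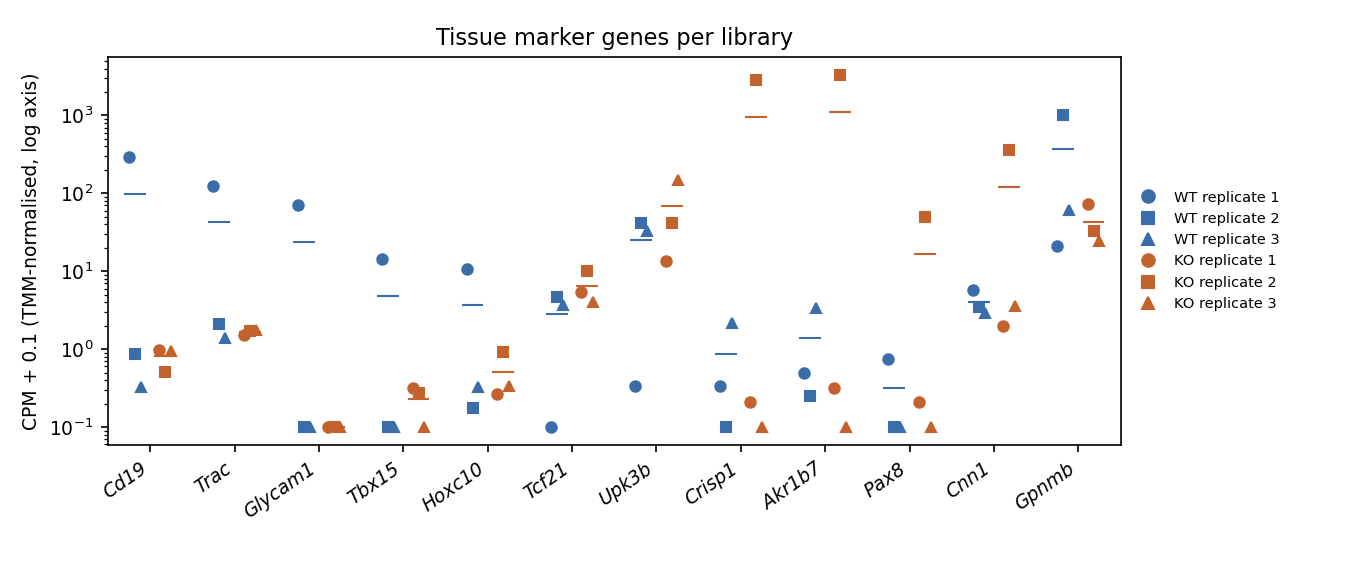
CPM plus 0.1 per library on a log axis for marker genes of lymphocytes, lymph node, fat depots, mesothelium, epididymis, smooth muscle and lipid-associated macrophages, with a symbol per replicate and a line at each group mean. Cd19, Trac and Glycam1 are high in WT replicate 1, Crisp1, Akr1b7, Pax8 and Cnn1 in KO replicate 2, and Gpnmb in WT replicate 2.

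Among the lists that fell, thermogenic and beige adipocyte genes were led by Kcnk3, a potassium channel that limits adipocyte thermogenesis. Kcnk3 was at 57.8 ± 6.00 CPM in WT and 26.0 ± 7.19 CPM in KO-labelled libraries (-1.15 ± 0.25). Cpt1b, the muscle and brown fat form of the enzyme that admits fatty acids to mitochondria, was at 15.5, 7.71 and 6.81 CPM and at 1.97, 3.59 and 3.19 CPM (-1.77 ± 0.44). Cidea (61.3 CPM in WT replicate 1; -3.32 ± 1.09) and Cox8b (29.8 CPM in WT replicate 1; -2.67 ± 0.90), both brown fat markers, were -1.40 ± 0.61 and -1.43 ± 0.66 without that library. In WT replicate 3 they were at 2.45 and 1.99 CPM, inside the range of KO-labelled libraries (2.25 to 2.80 and 1.68 to 2.41 CPM). The fall left without WT replicate 1 thus rested on WT replicate 2, at 10.7 and 9.77 CPM. Of 12 members tested 9 were negative (median -0.32, adjusted p = 0.00138, camera; adjusted p = 0.855 with an estimated correlation). Kcnk3 and Cpt1b passed adjusted over the list alone, and 0 passed over all genes. The call ended without WT replicate 1 (median -0.30), and the median was -0.98 without WT replicate 3 and -0.89 without KO replicate 2, where 17 and 15 members passed the expression filter in place of 12. Skeletal muscle genes did not pass as a list (median -0.73, adjusted p = 0.681, camera, and median 0.27 without WT replicate 1). Their member Actn3 (1.57 ± 0.42), of fast muscle fibres, passed adjusted over the list alone. It had few counts, 6, 6 and 5 in WT and 25, 28 and 12 in KO-labelled libraries. Plin5 also passed adjusted over the list alone, among genes of triglyceride synthesis and lipid droplets. Over all lists, 4 such members were found among 570 tested.

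Lipid-associated macrophage genes and matrix genes fell as lists. All 16 macrophage genes were negative (median -0.97, adjusted p = 0.000357, camera; adjusted p = 0.891 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, was at 20.9, 1022 and 60.4 CPM in WT and at 72.2, 32.3 and 24.2 CPM in KO-labelled libraries (-3.09 ± 1.41). Atp6v0d2 (-3.04 ± 1.53), a lysosomal proton pump subunit, and Itgax (-2.49 ± 1.03), which encodes CD11c, were also highest in WT replicate 2, at 105 and 107 CPM, and the protease Ctsk was -1.25 ± 0.57. Without WT replicate 2 camera turned to the other direction (median 0.14), and Gpnmb was 0.08 ± 0.64, Atp6v0d2 0.03, Itgax -1.06 and Ctsk -0.56. Itgax was -3.81 without KO replicate 1. Of 25 matrix genes 21 were negative (median -0.43, adjusted p = 0.00182, camera; adjusted p = 0.891 with an estimated correlation), among them the collagen Col6a3 (-0.89 ± 0.42), periostin (Postn, -0.81 ± 0.41), Mmp3 (-2.25 ± 0.84) and Tgfb1 (-0.50 ± 0.41). Without WT replicate 1 Mmp3 was -0.93 ± 0.54 and Tgfb1 -0.14 ± 0.39, without WT replicate 2 Postn was -0.38 ± 0.37, and without KO replicate 1 Col6a3 was -1.41 and Tgfb1 -0.91. The matrix call ended without WT replicate 2 (median -0.11) and without KO replicate 2 (-0.19), and the median was -0.79 without WT replicate 1. In both lists 0 members passed over all genes or adjusted over the list alone.

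Genes of B and plasma cells, the cell cycle and erythroid cells fell as lists too. B cell genes were high in WT replicate 1 alone: Cd22 was at 134 CPM there and at 0.348 to 4.50 CPM elsewhere (-6.15 ± 1.87). Cd19 (-7.09 ± 2.62), Cd79b (-6.00 ± 2.28) and the immunoglobulin gene Igkc (-2.46 ± 1.17) gave 291, 152 and 325 CPM in that library. All 6 tested members were negative (median -4.23, adjusted p = 0.000688 by camera and 0.855 with an estimated correlation). Without WT replicate 1 the call ended (median -0.04), with Cd22 at -2.17, Cd19 at 0.51, Cd79b at 0.05 and Igkc at -0.13. Without WT replicate 3 the median was -6.57. All 20 cell cycle genes were negative (median -0.45, adjusted p = 0.000130, camera; adjusted p = 0.891 with an estimated correlation), led by the mitotic kinase Plk1 (-1.85 ± 0.56), Birc5 (-1.35 ± 0.77), Mki67 (-0.89 ± 0.52) and Ube2c (-0.85 ± 0.52). The cell cycle call ended without WT replicate 1 (median -0.26), the library with the lymphocyte genes, and the median was -0.72 without KO replicate 1. Birc5 was -0.86 without KO replicate 2, Ube2c -0.47 without WT replicate 2 and -1.33 without KO replicate 1, and Mki67 -0.60 ± 0.55 without WT replicate 1. Haemoglobin genes, which mark blood in the tissue, made up most of the erythroid list. All 5 of its tested members were negative (median -1.26, adjusted p = 0.00473, camera; adjusted p = 0.855 with an estimated correlation), with Hbb-bs at 144, 208 and 23.9 CPM in WT and 38.9, 67.8 and 41.3 CPM in KO-labelled libraries (-1.34 ± 0.71), and Hba-a1, Hba-a2 and Hbb-bt at -1.29, -1.26 and -1.21. Without WT replicate 2 these 4 genes were at -0.75, -0.58, -0.61 and -0.69. The erythroid call ended without WT replicate 1 (median -1.21), WT replicate 2 (-0.61) or KO replicate 1 (-1.07), and with titles of 3-digit numbers alone, which leave 1 WT library, camera turned to the other direction (0.95). In each of the 3 lists 0 members passed over all genes or adjusted over the list alone.

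**Figure D3:**
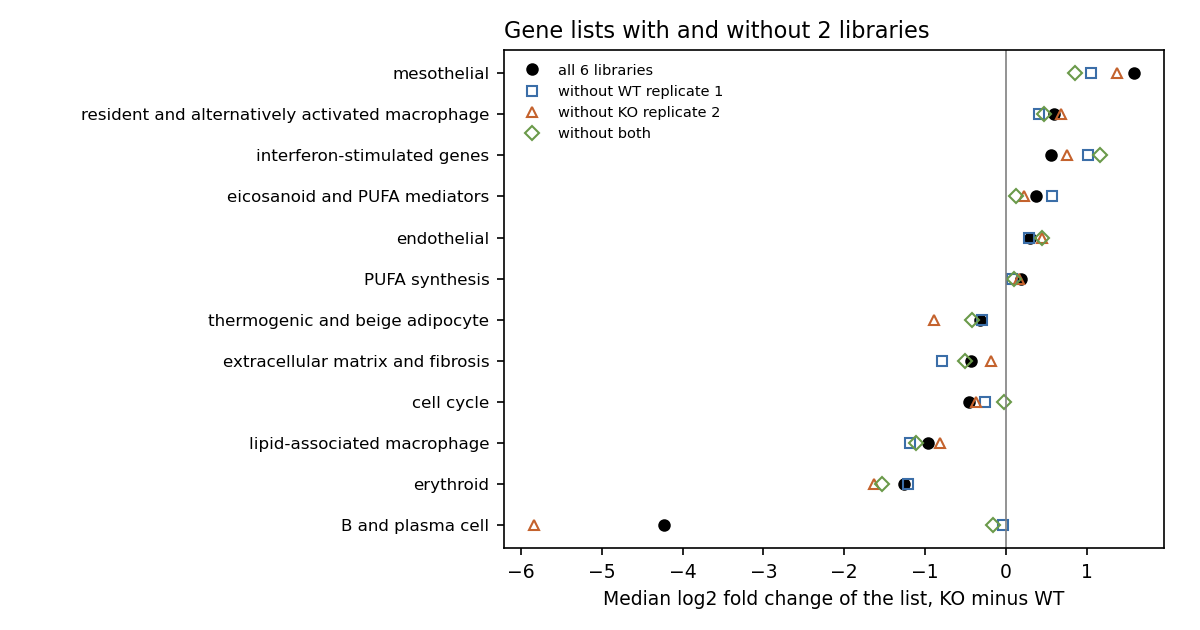
Median log2 fold change, KO minus WT, of the 12 lists past the camera threshold, with all 6 libraries (black), without WT replicate 1, without KO replicate 2 and without both (open symbols). The median of B and plasma cell genes moves from -4.23 to -0.04 without WT replicate 1, and that of interferon-stimulated genes from 0.55 to 1.02.

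The lists that did not pass hold the main lipid pathways of the adipocyte. Genes of de novo lipogenesis, such as the acetyl-CoA carboxylase Acaca (0.37 ± 0.24) and the malic enzyme Me1 (-0.46 ± 0.41), had a median of -0.01 (adjusted p = 0.681, camera). Acaca was 0.16 without KO replicate 3, and Me1 was -0.81 without WT replicate 1 and -0.15 without WT replicate 3. The list passed downward without WT replicate 1 (median -0.17), without WT replicate 1 and KO replicate 2 together (-0.38) and with titles of 3-digit numbers alone (-0.37), and upward without WT replicate 3 (0.31, adjusted p = 0.0430). Fatty acid oxidation (median -0.04, adjusted p = 0.896) joined Ehhadh at 0.67 ± 0.15 with Cpt1b at -1.77 ± 0.44. The mixed test of fry asks whether members change in either direction. In that test 7 lists passed without WT replicate 1, and 2 without WT replicate 1 and KO replicate 2 together. With all 6 libraries, fatty acid oxidation was the 1 list past the threshold of the mixed test (adjusted p = 0.0402). That call ended with no filter, with titles of 3-digit numbers alone and without any single library other than WT replicate 1 (adjusted p 0.0252 to 0.895 over the alternatives). Cholesterol synthesis, with Fdft1 and the methylsterol oxidase Msmo1 (0.66 ± 0.28; 0.44 without WT replicate 1), had a median of 0.09 (adjusted p = 0.209). It passed upward without KO replicate 3 (median 0.20, adjusted p = 0.00155) and with no filter (0.17, adjusted p = 0.0415), and its median was -0.07 without KO replicate 2. Mature adipocyte genes had a median of 0.13 (adjusted p = 0.387). They passed upward without WT replicate 3 (0.35, adjusted p = 0.00298) and without KO replicate 2 (0.22, adjusted p = 0.0458), and downward with titles of 3-digit numbers alone (-0.39, adjusted p = 0.00146). Mitochondrially encoded genes had a median of -0.26 (adjusted p = 0.369), with mt-Nd2 at -0.61 ± 0.35 (-0.33 without WT replicate 1). They passed downward without WT replicate 2 (median -0.49, adjusted p = 0.00254). T and NK cell genes, led by Trac (-4.78; -0.07 without WT replicate 1) and Cd2 (-3.52; -0.61), had a median of -3.93 (adjusted p = 0.0947). They passed downward without WT replicate 2 (-4.49, adjusted p = 7.07e-05), without WT replicate 3 (-4.50, adjusted p = 0.000124) and with no filter (-3.85, adjusted p = 0.0220). Without WT replicate 1, which held 126 CPM of Trac and the mitochondrial share of 14.5%, these 2 lists passed upward, with medians of 0.44 and 1.56. They also passed upward without KO replicate 2 as well (0.47 and 1.46) and with titles of 3-digit numbers alone (0.37 and 1.33). In none of these sets did a list pass with an estimated correlation, and the smallest adjusted p with an estimated correlation was 0.473, of T and NK cell genes without WT replicate 1. Smooth muscle genes did not pass (median 0.01, adjusted p = 0.567), but passed downward without KO replicate 2 (-0.25, adjusted p = 0.0458) and upward without KO replicate 3 (0.34, adjusted p = 0.00424). Their member Myh11 was at 1996 CPM in KO replicate 2 and at 50.1 to 128 CPM elsewhere. The 16 further lists had medians from -1.68 (mast cell) to 0.18 (neutrophil) and adjusted p from 0.158 (dendritic cell) to 0.998 (macrophage). With 1 library left out, macrophage, dendritic cell, mast cell, neutrophil, fibroblast and insulin signalling genes each passed in at least 1 set. The list of epididymis and accessory gland genes had 0 members past the expression filter.

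Of the 36 lists tested, 12 passed with the preset correlation, 6 upward and 6 downward. With a correlation estimated from the data 0 passed (smallest adjusted p 0.855), and by the directional test of fry 0 passed (0.995). Median, mean and test had the same sign in all 12, and differed in sign in 11 of the 24 that did not pass. Without WT replicate 1, 7 lists passed, of which 4 were among the 12 (interferon-stimulated, endothelial, lipid-associated macrophage and matrix genes). Without WT replicate 1 and KO replicate 2 together 11 passed, of which 6 were among the 12, the same 4 with thermogenic and resident macrophage genes, while camera turned for PUFA synthesis. With titles of 3-digit numbers alone (1 WT and 3 KO), the calls of PUFA synthesis, thermogenic, lipid-associated macrophage, endothelial and mesothelial genes ended. Eicosanoid, interferon-stimulated, matrix and resident macrophage genes kept theirs, and lists outside the 12 passed as well. Cell cycle, B and plasma cell and erythroid genes turned to the other direction. In each of these sets 0 lists passed with an estimated correlation.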

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

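The removal of WT replicate 1 and KO replicate 2 together was chosen after their marker genes were seen; the other alternatives were planned. The direction of a list is camera's, while the value given is its median log2 fold change, so the signs can differ. The count of 0 changed genes by edgeR held under 3 other scalings, 2 other filters, each library left out, 3-digit titles alone, and the joint removal. Other scalings placed the median log2 fold change of all genes between -0.03 and 0.03. DESeq2 called 13 genes, 7 higher and 6 lower, and the exact test 2, both of which were higher. Ilf3 stayed between -0.16 and -0.03 in all alternatives run. Over 72 genes rerun by name besides Ilf3, 1177 results kept direction and side of the threshold, 10 passed it (Ccdc50 and Gm28539 in DESeq2 and the exact test, and Plin5, Sfrp1, Dkk3, Trpv2, Tnfaip3 and Dock8 in DESeq2) and 34 turned; Ucp1, called by DESeq2, had no main value to compare. For the 19 lists described singly besides PUFA synthesis, 145 results held, 10 passed, 45 no longer passed and 28 turned. Lists past the threshold numbered 0 with an estimated correlation and 0 by fry, and 7 (without WT replicate 1) to 18 (without WT replicate 3) with each library left out. PUFA synthesis, at a median of 0.18, was no longer past it with an estimated correlation or by fry. Nor was it without KO replicate 2 (median 0.16) or with 3-digit titles (0.12). Camera turned without WT replicate 1 (0.072) and with the joint removal (0.11). The median of PUFA synthesis was 0.072 to 0.33 with each library left out. Across sets of libraries the smallest adjusted p of any list with an estimated correlation was 0.473 (without WT replicate 1) to 0.995 (without KO replicate 1). With each library left out in turn, genes that changed sign spanned -3.16 to 1.29 (Timd4), -7.66 to 0.51 (Cd19), -6.78 to 0.047 (Cd79b), -3.69 to 0.081 (Gpnmb), -3.91 to 0.029 (Atp6v0d2), -0.48 to 7.08 (Ptgs2), -0.67 to 3.42 (Myh11), -0.56 to 5.53 (Cnn1) and -0.0081 to 0.29 (Elovl5). Lists that turned spanned -0.17 to 0.31 (de novo lipogenesis), -0.13 to 0.024 (fatty acid oxidation), -0.49 to 0.44 (mitochondrially encoded), -0.22 to 0.35 (mature adipocyte), -4.50 to 1.56 (T and NK cell), -0.25 to 0.34 (smooth muscle), -0.96 to 0.27 (skeletal muscle; turned at -0.96 without WT replicate 2 and -0.68 without WT replicate 3) and -1.23 to 0.14 (lipid-associated macrophage). Titles of 3-digit numbers leave 1 WT library, assumed to vary like the KO libraries, and turned Cidea (0.0028), Cox8b (0.11), Mmp3 (0.090), Tgfb1 (0.22), Mki67 (0.27), Ctsk (0.13), Timd4 (1.01), Cd19 (1.58), Cd79b (1.31), Igkc (1.10), Hbb-bs (1.04), Hba-a2 (0.84), Hba-a1 (0.86), Hbb-bt (1.14) and Trac (0.25). It also turned de novo lipogenesis (-0.37), cholesterol synthesis (0.14), fatty acid oxidation (-0.14), mitochondrially encoded (0.37), cell cycle (0.26), mature adipocyte (-0.39), T and NK cell (1.33), smooth muscle (-0.10), B and plasma cell (0.76) and erythroid genes (0.95). The joint removal turned Ptgs2 (-1.01), Tgfb1 (0.013), Timd4 (1.52), Cd163 (-0.13), Cd19 (0.79), Cd79b (0.23), Myh11 (-0.54) and Cnn1 (-0.22), and de novo lipogenesis (-0.38), cholesterol synthesis (-0.10), fatty acid oxidation (-0.13), mitochondrially encoded (0.47), mature adipocyte (-0.078), smooth muscle (-0.25) and T and NK cell genes (1.46). Limma voom turned Timd4 (1.11) and Cd19 (0.050), and gave WT replicate 1 a weight of 0.194. Cd19, Cd79b and Timd4 (WT replicate 1), Gpnmb and Atp6v0d2 (WT replicate 2), and Myh11, Cnn1 and Ptgs2 (KO replicate 2) turned on removal of the 1 library with the high value; for the rest, the cause was not tested. No paired analysis was possible because the labels give no shared replicate numbers. Depth (12669584 to 17806107 counts) was not varied in the simulations. At this depth, simulated 2-fold changes were recovered for 1.37% of genes with the spread of 6 libraries and for 31.5% with that of the 4 left by the joint removal. Both simulations had 6 libraries, so 31.5% is not the recovery of a comparison of those 4.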

Other observations

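The chromosome 16 region and the tests of Fads2 and Ilf3 below were chosen after the results were seen; the tests of WT replicate 1, of duct tissue and of other splits had their outcomes written down before they were run. Ccdc50 and Gm28539, the 2 genes called by both DESeq2 and the exact test, lie on chromosome 16 (27388869 to 27452218 and 18836584 to 18956247). Gm28539, an annotated gene without an assigned name, was at 0.239, 0.229 and 0.459 CPM in WT and 1.92, 2.90 and 3.12 CPM in KO-labelled libraries. Between these genes lie Ehhadh, Rtp4 and Masp1, a protease of the lectin pathway of complement, with log2 fold changes of 0.67 ± 0.15, 1.29 ± 0.34 and 1.33 ± 0.53; Masp1 was 0.68 without WT replicate 1 and KO replicate 2 together. All 3 lay above WT in every KO-labelled library, and Bcl6, a transcriptional repressor in the same span, lay below (-0.81 ± 0.24). Of 70 genes tested in the span, 10 lay wholly above WT (14.3%, against 4.02% of all genes tested) and 1 wholly below, so most overlapped. Because the span was set by genes chosen for their values, its share of such genes tests nothing. The span also holds Adipoq, whose promoter is often used to express Cre in adipocytes; the labels used here do not name the Cre line. A difference in haplotype between the groups there was not tested, since the table holds no sequence variants, and it stays open for Ccdc50, Gm28539, Ehhadh, Rtp4, Masp1 and Bcl6.

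Among genes called by DESeq2 alone, all named after their values were seen, Sfrp1 and Dkk3, which are secreted modulators of Wnt signalling, had edgeR log2 fold changes of 2.05 and 1.94. Trpv2, a cation channel, Tnfaip3, a brake on NF-kappaB signalling, and Dock8, of leukocyte migration, had -1.13, -1.68 and -2.36. Ucp1, the uncoupling protein of thermogenic fat, was at 5.34, 11.3 and 0.306 CPM in WT and 0, 0.0579 and 0.234 CPM in KO-labelled libraries, too low for the edgeR filter. Asns, the asparagine synthetase of the integrated stress response, lay above WT in every KO-labelled library (0.76 ± 0.22), without passing the edgeR test.

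WT replicate 1 combined lymphocyte genes, a low level of mesothelial genes and 1257 CPM of adiponectin (Adipoq), against 2506 to 3747 CPM elsewhere. A female animal was excluded, because Y-linked genes summed to 242 CPM and Xist was at 0.398 CPM. Lymph node tissue may be present: over 8 lymph node genes outside the fixed lists, the median log2 excess over the highest other library was 4.98, with Glycam1 at 69.9 CPM (0 in the other 5 libraries), Ccl21a at 161 CPM and Ccl19 at 96.8 CPM. Tissue of a subcutaneous depot may be present too: Tbx15, Shox2, En1 and Hoxc10 had a median log2 excess of 4.34 over the mean of the other libraries, and the 2 visceral genes one of -3.20, set by Tcf21 at 0 CPM, while Nr2f1 was at 4.70 CPM against 7.25 to 9.15 CPM elsewhere. A mislabelled sample, whose columns were matched by a number without a group name, and a dissection that took in a lymph node with its fat were not set against each other, and no biological explanation was tested.

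KO replicate 2 alone carried high Fads1 and Fads2, the desaturases of PUFA synthesis. Without this library the log2 fold change of Fads2 was 0.25 ± 0.35, and without WT replicate 1 as well it was 0.56 ± 0.21; the 95% interval of the former reaches 1.13 and also covers 0, so an effect of the genotype stays open. Epididymal duct or vas deferens tissue in the sample may account for the pattern: 6 of 7 duct epithelium genes outside the fixed lists met the criterion of 3 counts and 4 times the next library, among them Pax8 at 50.0 CPM and Pax2 at 32.3 CPM. Eppin and Atp6v1b1 met it with only 4 and 8 counts. Cftr, which missed the criterion, was at 1.01 CPM in KO replicate 3 and at 0.348 CPM in KO replicate 2. Akr1b7 (3349 CPM), Crisp1 (2865 CPM) and Myh11 (1996 CPM) were among the abundant transcripts of duct and muscle there, whereas the epididymal genes Lcn8, Crisp4 and Adam7 were at 0. Whether the desaturase transcripts themselves come from duct cells could not be tested in bulk tissue.

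Ilf3 did not differ detectably between the libraries labelled KO and WT (log2 fold change -0.088 over the whole gene). Reads from cells other than adipocytes may hide a loss in adipocytes, and the lower bound of -0.48 leaves room for a drop of up to 28.1%. A deletion that leaves most of the transcript in the count is also possible and cannot be told apart from the former, because the table has whole-gene values only. Ilf3 spanned 34.3 to 40.6 CPM over all 6 libraries. No biological explanation was tested.

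The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 changed genes and the highest of the others gave 0. With 0 in the real split, every other split had to give at least as many, so this comparison decides nothing. At an unadjusted p under 0.05 (edgeR) the real split gave 512 genes and the others 372 to 1639.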
